A study of Cucumis melo with 24 samples.

How the data were processed

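RNA was measured in fruit of greenhouse-grown oriental melon plants, in 24 libraries made from polyadenylated RNA with a SMARTER mRNA-Seq kit, per the labels' protocols. The labels give each library's cultivar (HS or LW), day (15, 25, 30 or 35) and number within its group, and these set the 8 groups of 3.

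A table of raw gene counts and a table of FPKM were deposited by the authors, both with 31374 entries and 24 columns. The counts are whole numbers per gene with no normalization. The FPKM values deposited by the authors relate a gene's fragments to its length and to the library's mapped fragments, so by the definition of the unit each library is scaled by its total alone. HISAT2 (version 2.0.5) and DESeq2 (version 1.20.0) are named in the submitters' processing notes. The genome build, the annotation, the counting program and its strand setting are not given in the sources used here, so reads from overlapping or near-identical genes cannot be told apart in these counts. Of the entries, 29975 carry identifiers that begin with MELO3C and 1399 identifiers of the form Cucumis_melo_newGene followed by a number, whose meaning the files do not state. Each table held repeated header lines between its entries, 4 in the table of counts. In these the letters before the day differ from those of the header at the top. These lines were dropped, and the columns were matched to the libraries by the names in the header at the top. Those names give the day, the number and 1 letter for the cultivar, L or H, read as the first letter of LW or HS; if the letters stood for the cultivars the other way round, every direction between HS and LW would turn. Columns matched to no library numbered 0. A value of 0 in one table and not in the other occurred in 7 cells.

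Counts were tested with edgeR (version 4.0.16, in R 4.3.3) as deposited. Entries were kept with filterByExpr on the 8 groups, which left 19520, of which 911 were newGene entries; 7158 entries had no count in any library. Libraries were scaled with TMM factors, which ran from 0.792 to 1.31, and the common biological coefficient of variation was 21%. All 24 libraries entered 1 fit of 8 group means with glmQLFit, and 14 contrasts were tested with glmQLFTest and Benjamini-Hochberg adjustment, with calls at an adjusted p under 0.05. The contrasts were HS minus LW at each day and over the mean of the days, the changes from 15 d to 35 d and between neighbouring days in each cultivar, and the difference between the cultivars' changes from 15 d to 35 d. These contrasts, the test and the threshold were fixed before the data were examined. TMM assumes that most genes do not differ, and 71.2% and 74.1% of genes were called from 15 d to 35 d in HS and LW; with library totals alone the median log2 difference of all tested genes moved to -0.66 for HS 25 d minus 15 d, -0.62 for LW 35 d minus 15 d and -0.61 for HS minus LW at 25 d, and directions are given relative to the TMM scale.

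Genes to be named were set by a rule: per comparison, the genes with the largest change among those called, with a mean of at least 10 FPKM in the highest group compared and, outside the difference of changes, no overlap of the groups' libraries. The rule asked for a product name, and for at most 2 identifiers each way where none could be had. A table of RefSeq genes (assembly USDA_Cmelo_AY_1.0, 28628 genes) matched 0 of the identifiers, so the second form applied. For the same reason the 29 gene lists that had been fixed by product name, among them sucrose synthesis and cleavage, ethylene synthesis and signalling, and MYB and MADS-box factors, had 0 members, and no gene list was tested. Levels are mean FPKM as deposited with the SD over 3 libraries. A fold against a group with 0 counts is a lower bound from 3 counts over that group, on the TMM scale, and covers counting error only, since reads were counted without molecular identifiers.

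The edgeR step was tested on simulated counts for HS minus LW at 35 d, drawn for the 19520 genes from the libraries' means and sizes with 50 genes changed at each of 4 sizes. It recovered 28% of the genes changed 1.5-fold, 68% of those changed 2-fold, 94% at 4-fold and 98% at 8-fold, and 7 unchanged genes were called (4.64% of the calls). The changed genes were drawn from those above a minimum expected count, and all others were equal between the 2 groups. In the data 53.2% of genes were called in this comparison, so these rates need not hold for it.

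Alternatives were RLE and upper-quartile factors, no filter, DESeq2 (version 1.42.0) and limma (version 3.58.1). The limma fits used log2(FPKM + 1) with and without a filter and log2(FPKM + 0.1) with a filter. Further alternatives were a fit of the compared groups alone, the replicate number as a block, at least a 2-fold change, and each library left out in turn. Library totals alone and a fit without the newGene entries were added after the data had been seen. The overlap of lists was set beside the product of their sizes over the genes tested. Principal components were computed on log2 CPM with a prior count of 2. Replicate libraries were checked for duplicates with a chi-square of their counts per degree of freedom, which ran from 12.2 to 157, so no pair was counted as 1.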

Results

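The study compared fruit of 2 cultivars of oriental melon (Cucumis melo), HS, described in the labels as high in sucrose, and LW, described as low in sucrose. Fruit of each cultivar was sampled at 15, 25, 30 and 35 d, and the labels do not state from which event the days were counted. Each of the 8 groups held 3 libraries of polyadenylated RNA, 24 libraries in all. The total count per library ranged from 30734462 to 36405629, and between 18422 and 20051 of the 31374 entries had at least 1 count in a library. The labels number the libraries of a group without saying that they came from separate plants or fruits, so p-values measure only the spread between these libraries, which may be technical. The files pair no gene identifier with a gene name or product, so genes are given by identifier. The values of MYB113 and MADS26, the transcription factors in the title of the series, were not analysed here for that reason.

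Libraries of a group lay together, and over the whole span of days sampling day separated them more than cultivar did. Between the last 2 days this was not so. From 30 d to 35 d 4811 genes were called in HS and 8465 in LW, against 10701 and 10389 between the cultivars at 30 d and 35 d. The first principal component of log2 CPM held 50.5% of the variance and ran from the 15 d libraries of both cultivars to the LW 35 d and the HS 30 d and 35 d libraries, which overlapped on it. The second held 14.6%, with the HS libraries on the negative side and the LW libraries on the positive side. Within groups, pairs of libraries correlated at 0.967 to 0.985 across genes, and no pair differed as little as sampling noise would give. The most counted genes, taken anew in each library, held a larger share of the counts at 35 d than at 15 d. The 10 most counted genes of a library held 6.07% ± 0.9 (SD, n = 3) of the counts in HS at 15 d and 10.8% ± 0.77 at 35 d, against 5.06% ± 0.41 and 9.49% ± 0.43 in LW. At 25 d and 30 d the means were 6.17% and 10.9% in HS and 5.5% and 7.18% in LW.

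**Figure D1:**
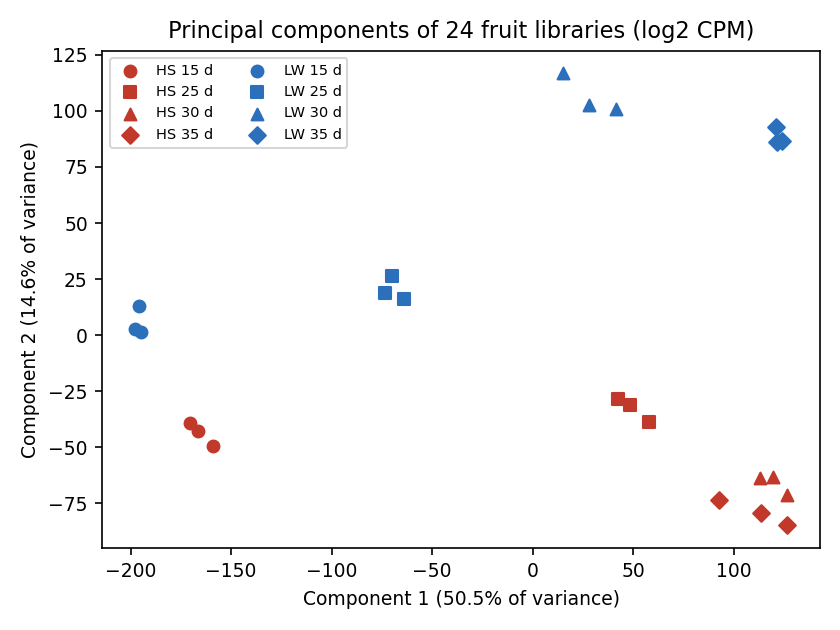
Each point is 1 library, placed by its scores on the first (horizontal, 50.5% of the variance) and second (vertical, 14.6%) principal components of log2 CPM, with colour for the cultivar and shape for the sampling day. The 15 d libraries of both cultivars lie at the left, and the LW libraries lie above the HS libraries.

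At 15 d, the question was which genes differed between the cultivars in the youngest fruit. Cucumis_melo_newGene_2368 stood at 17.2 ± 2.7 FPKM (SD, n = 3) in HS and had 0 counts in the LW libraries of this day, at least 1340-fold higher in HS. Cucumis_melo_newGene_823 was at 35.4 ± 2.9 FPKM in HS and at 0 counts in LW, at least 872-fold higher. On the other side, MELO3C034903.2 was at 22.8 ± 4.2 FPKM and MELO3C035524.2 at 12.4 ± 1.1 FPKM in LW, both with 0 counts in HS, at least 581-fold and at least 382-fold lower in HS. Cucumis_melo_newGene_2368 had 0 counts in the LW libraries at all 4 days, and MELO3C034903.2 and MELO3C035524.2 had 0 counts in the HS libraries at all 4 days. In all, 7334 of 19520 genes tested (37.6%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 3684 higher in HS and 3650 lower, and 2810 of them differed at least 2-fold. This was the day with the fewest genes called between the cultivars.

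At 25 d more genes were called between the cultivars than at any other day sampled. The counts of the days were not tested against each other. The genes named as higher in HS were Cucumis_melo_newGene_665, at 26.6 ± 2 FPKM (SD, n = 3) in HS against 0 counts in LW and so at least 3310-fold higher, and MELO3C021492.2, at 15.7 ± 4 FPKM against 0 counts and at least 755-fold higher. MELO3C021492.2 went on to 39.4 ± 14 FPKM in HS at 30 d, while the LW libraries held 2 counts of it in all at 30 d and 6 at 35 d. Cucumis_melo_newGene_2767 and Cucumis_melo_newGene_1922 were at 16.2 ± 2 and 17.9 ± 5.9 FPKM in LW with 0 counts in HS, at least 745-fold and at least 594-fold lower in HS. The test called 11444 genes (58.6%), 5605 higher in HS and 5839 lower, and 6019 of them differed at least 2-fold. The balance of directions rested on the scaling of the libraries: 49% of the called genes were higher in HS with TMM factors, 37.8% with upper-quartile factors and 19.7% with library totals alone.

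At 30 d, MELO3C016595.2 reached 60.9 ± 11 FPKM (SD, n = 3) in HS with 0 counts in LW, at least 4530-fold higher. MELO3C029161.2 was at 11.5 ± 0.52 FPKM in HS and at 0 counts in LW, at least 503-fold higher. Lower in HS were Cucumis_melo_newGene_2767, at least 882-fold, and MELO3C012873.2, at least 767-fold, with 14.1 ± 3.3 and 37.8 ± 5.8 FPKM in LW and 0 counts in HS. MELO3C012873.2 had been expressed in HS earlier, at 20.1 ± 4.4 FPKM at 15 d, when LW had 7.31 ± 4.3 FPKM. In this comparison 10701 genes passed the test (54.8%), 5349 higher in HS and 5352 lower. Of these, 5277 differed at least 2-fold, 1950 higher and 3327 lower. Higher calls made up 50% with TMM factors and 40.1% with library totals alone.

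At 35 d, the oldest fruit, Cucumis_melo_newGene_2368 was again among the genes named by the rule, at 11.4 ± 0.57 FPKM (SD, n = 3) in HS and at least 677-fold higher than in LW. MELO3C008183.2 was called at least 953-fold higher in HS, where its libraries held 19, 520 and 2781 counts against 0 in LW, so its level in HS was spread over more than its own mean (61.7 ± 81 FPKM). Its fitted log2 difference was 13.17 with all libraries and 11.2 without HS replicate 3. MELO3C033189.2 and MELO3C013292.2 were lower in HS, at least 742-fold and at least 681-fold. Both rose late in LW, from 0.739 ± 0.21 and 1.63 ± 0.33 FPKM at 30 d to 10.1 ± 2.8 and 16.7 ± 4.3 FPKM at 35 d, and both had 0 counts in the HS libraries of all 4 days. The test called 10389 genes (53.2%), 5258 higher in HS and 5131 lower, 5195 of them by at least 2-fold. Higher calls made up 50.6% with TMM factors and 62.1% with library totals alone.

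Few genes were called in the same direction between the cultivars at every day, though a day without a call is no change of direction. Of the 19520 genes tested, 471 were called higher in HS at each of the 4 days and 397 were called lower at each, where independent lists of the same sizes would share 78.1 and 78.7. Another 6293 genes were called higher in HS at some day and lower at another. Only 2270 genes were called at no day, while 4081 were called at 1 day, 5823 at 2, 5243 at 3 and 2103 at 4. For the mean of the 4 cultivar differences, edgeR called 11407 genes (58.4%), 5861 higher in HS and 5546 lower, and 3153 of them differed at least 2-fold, 1042 higher and 2111 lower. With library totals alone, 33.9% of the called genes were higher in HS, against 51.4% with TMM factors.

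**Figure D2:**
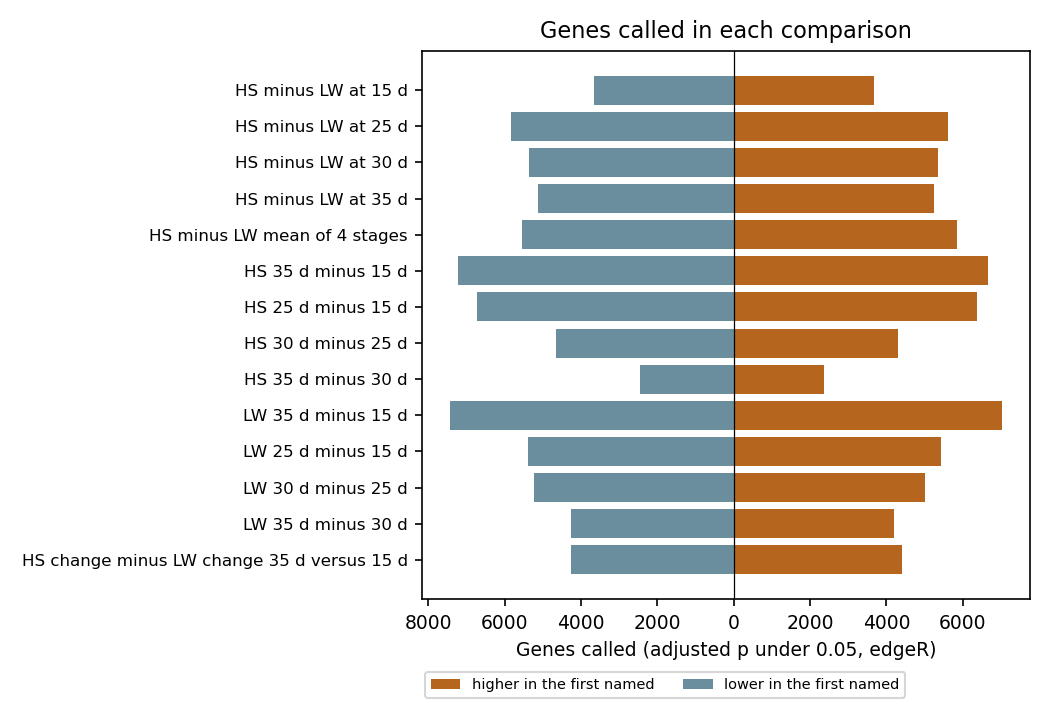
Bars give the number of genes called in each comparison (horizontal axis, genes at an adjusted p under 0.05 in edgeR), to the right of 0 for genes higher in the condition named first and to the left for genes lower. The longest bars are the changes from 15 d to 35 d, with 13895 genes called in HS and 14468 in LW, and the shortest is the last step in HS, with 4811.

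Over the sampled development of HS, MELO3C016595.2 and MELO3C034862.2 had the largest fitted rises among the genes that met the naming rule. They had 0 counts at 15 d and reached 118 ± 34 and 230 ± 25 FPKM (SD, n = 3) at 35 d, at least 10100-fold and at least 5090-fold higher. MELO3C023620.2 fell from 80.5 ± 23 FPKM and MELO3C008342.2 from 50.8 ± 18 FPKM at 15 d to 0 counts at 35 d, at least 3210-fold and at least 2380-fold lower. MELO3C023620.2 had only 36 counts in the LW libraries of 15 d. From 15 d to 35 d 13895 genes changed in HS (71.2%), 6673 rising and 7222 falling, and 8686 of them changed at least 2-fold. Rising genes were 48% of those called with TMM factors and 34% with library totals alone.

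Over the same interval in LW, MELO3C013129.2 went from 0 counts to 668 ± 200 FPKM (SD, n = 3), at least 54700-fold higher, and MELO3C018490.2 from 0 counts to 316 ± 21 FPKM, at least 30800-fold higher. Both also rose in HS, to 74.8 ± 10 and 138 ± 16 FPKM at 35 d. In HS, MELO3C018490.2 had stood higher at 30 d, at 544 ± 100 FPKM. MELO3C010312.2 fell from 274 ± 79 FPKM and MELO3C022376.2 from 66.1 ± 17 FPKM to 0 counts, at least 6860-fold and at least 2760-fold lower. In LW 14468 genes changed (74.1%), 7031 rising and 7437 falling, with 9533 changed at least 2-fold. Rising genes were 48.6% of those called with TMM factors and 29.5% with library totals alone.

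Both cultivars changed at each step between neighbouring days, and fewer genes were called at later steps. The first step spans 10 d and the others 5 d. In HS 13093 genes were called from 15 d to 25 d, 8963 from 25 d to 30 d and 4811 from 30 d to 35 d, of which 7906, 3746 and 1571 changed at least 2-fold. In LW 10807, 10261 and 8465 genes were called, and 5220, 4803 and 3757 of them changed at least 2-fold. The counts of the steps were not tested against each other. The share of rising genes lay between 48% and 50.2% in these 6 steps with TMM factors. Among genes changed at least 2-fold, fewer rose than fell: 3359 against 4547, 1323 against 2423 and 749 against 822 in HS, and 2206 against 3014, 2396 against 2407 and 1336 against 2421 in LW. With library totals alone, rising genes were 24.9% of all called for the 15 d to 25 d step of HS (38.3% with upper-quartile factors) and 77.3% for its last step. In LW they were 24% for the 25 d to 30 d step and 38.8% for the last step.

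Most genes that changed from 15 d to 35 d in both cultivars did so in the same direction. With TMM factors both cultivars rose in 4886 genes and both fell in 5175, where independent lists of these sizes would share 2404 and 2752. The balance rested on the scaling: with library totals alone, 2821 genes rose in both and 7344 fell in both. On the TMM scale, opposite changes were called in 569 genes that rose in HS and fell in LW and in 574 that fell in HS and rose in LW. The test of the difference between the changes passed in all of these. Choosing genes called in opposite directions in the same fit all but fixes that outcome.

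The difference between the 2 developmental changes, which asks whether the cultivars developed differently, was called in 8674 genes (44.4%), 4406 with a higher change in HS and 4268 with a lower one. Among the called genes, 818 rose in both cultivars but more in HS and 1197 more in LW, while 649 fell in both but more in HS and 1259 more in LW. A change was called in HS alone for 720 risers and 830 fallers, and in LW alone for 985 risers and 1013 fallers. MELO3C011268.2 rose from 0 counts to 119 ± 7.7 FPKM (SD, n = 3) in LW, while HS had 11.6 ± 2.7 FPKM at 25 d and 3.18 ± 0.29 at 35 d; the log2 change in HS was lower by 12.25 ± 1.23 (SE; edgeR adjusted p = 4.7e-07). MELO3C018228.2 fell in LW from 21.3 ± 14 FPKM to 0 counts and was at 1.08 ± 0.45 and 2.65 ± 3.7 FPKM in HS at 15 d and 35 d, a log2 difference of 13.27 ± 2.22 (edgeR adjusted p = 0.00011). Without HS 15 d replicate 2 the difference of MELO3C011268.2 was -11.48, and that of MELO3C018228.2 was 11.04 without HS 35 d replicate 3 and 12.65 without LW 15 d replicate 3. Each SE of a log2 value was derived from that value and the F statistic of its test in the fit of all 24 libraries. Fitted log2 values of genes with a group at 0 counts, and their SEs, depend on the fit and are no measured fold.

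MELO3C031534.2 and MELO3C021063.2 completed the genes named for this comparison, and both rested on uneven libraries. MELO3C031534.2 fell in HS from 29.4 ± 19 FPKM (SD, n = 3) to 0 counts, whereas the LW libraries held 218, 0 and 352 counts at 35 d and 0, 0 and 212 at 15 d. Its log2 difference was -12.8 ± 3.29 (SE; edgeR adjusted p = 0.0049), -21.52 without LW 15 d replicate 3, -12.2 and -12.21 without LW 15 d replicates 1 and 2, and -13.39 and -12 without LW 35 d replicates 2 and 3. MELO3C021063.2 rose in HS from 0 counts to 12.6 ± 2.5 FPKM, and its LW counts, 32 in all at 15 d, came from 1 library (replicate 2). The log2 difference of MELO3C021063.2 was 15.39 ± 4.31 (edgeR adjusted p = 0.012), and it fell to 9.22 with an adjusted p of 1 without that library and had an adjusted p of 0.099 in DESeq2. Over the 23 alternatives tried, its adjusted p ran from 0.00082 to 1. Higher changes in HS were 50.8% of the genes called in this comparison with TMM factors and 64.8% with library totals alone.

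**Figure D3:**
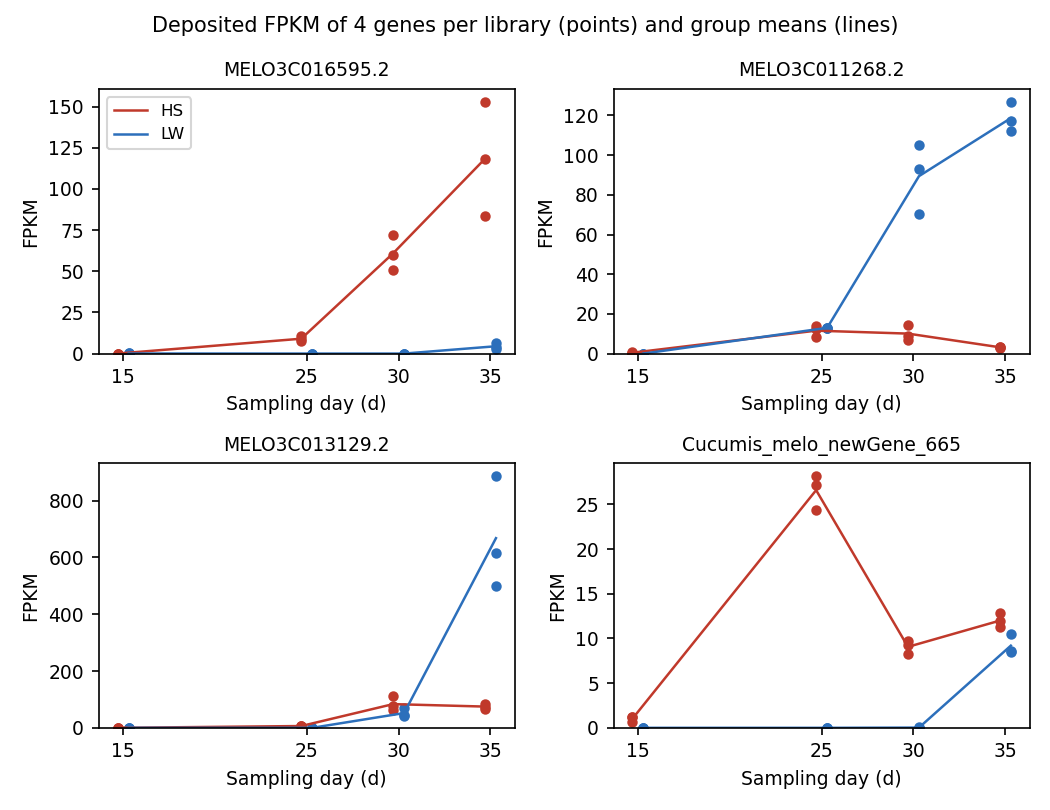
Deposited FPKM (vertical axes, linear) of 4 genes by sampling day (horizontal axes, d), with a point for each library and lines through the means of 3 libraries, HS in red and LW in blue. MELO3C016595.2 reached 118 FPKM in HS at 35 d and 4.46 FPKM in LW, while MELO3C011268.2 and MELO3C013129.2 were higher in LW at 35 d, and Cucumis_melo_newGene_665 was expressed in HS at 25 d and in LW only at 35 d above 1 FPKM.

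At the middle days, on the TMM scale, more of the genes with a shared direction were further along in HS than in LW. Of the 4886 genes that rose in both cultivars, 2742 (56.1%) were higher in HS at 25 d and 458 lower (median log2 difference 0.42). Among the 5175 that fell in both, 2850 (55.1%) were lower in HS at 25 d and 533 higher (median -0.78). At 30 d, 2330 of the rising genes were higher in HS and 679 lower, and 2271 of the falling genes were lower and 633 higher. These counts rested on the scaling. With library totals alone, the direction of the same 4886 rising genes turned at 25 d, with 1200 higher in HS and 1925 lower, and was kept at 30 d, with 1837 higher and 915 lower. Of the same 5175 falling genes, 3816 were then lower in HS and 230 higher at 25 d, and 2525 lower and 473 higher at 30 d.

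A position between 15 d and 35 d was computed for each library as the mean log2 CPM of the shared rising genes minus that of the shared falling genes, scaled so that a cultivar's own 15 d and 35 d means were 0 and 1. A factor common to all genes of a library cancels from this measure, apart from genes with counts near the prior count. At 25 d the position was 0.735 ± 0.024 (SD, n = 3) in HS and 0.4 ± 0.015 in LW, and at 30 d it was 0.99 ± 0.025 and 0.691 ± 0.046. The differences of 0.335 and 0.299 exceeded the spread between libraries, and every HS library lay above every LW library of its day. In a two-sided permutation test each gave p = 0.1, the smallest that 3 libraries against 3 allow. Over both days together, with the cultivars permuted within a day, the mean difference of 0.317 gave a permutation p of 0.005. That is the smallest that the 400 arrangements allow. The positions were scaled to each cultivar's own ends before the permutation and not scaled again. Libraries of a cultivar thus share the error of its ends at both days, so these permutation p-values are not exact. The position measure was chosen after the values had been seen.

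**Figure D4:**
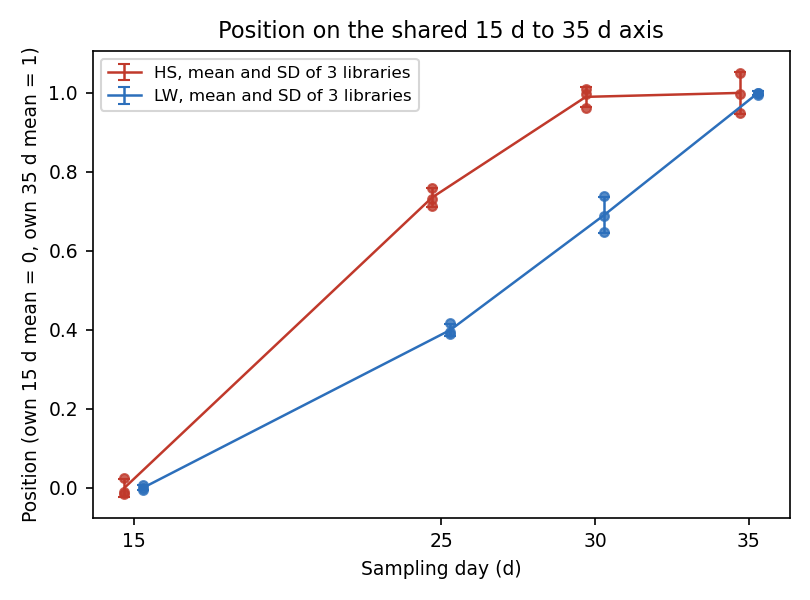
Points give the position of each library (vertical axis, no unit) by sampling day (horizontal axis, d), and lines with bars the mean and SD of 3 libraries, for HS in red and LW in blue. The scale sets each cultivar's own 15 d mean to 0 and its own 35 d mean to 1, and at 25 d HS stood at 0.735 and LW at 0.4.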

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

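The test of the difference between the cultivars' changes was fixed before the data were examined, while the comparison with other splits was read only after its result had been seen. Groups of 3 libraries were too small for a search for single outlying libraries. The change from 15 d to 35 d differed between HS and LW in 8674 of the 19520 genes tested. Of 30 splits of the 12 libraries of 15 d and 35 d within their days, only 1, the real one, called as many. A random grouping of these libraries into cultivars can thus be excluded at 0.05. The splits also mixed the cultivar difference within each day, so they do not test whether the changes differ between the cultivars. The highest of the others called 6484 genes. That split kept 2 of the 3 HS libraries in place at 15 d and reversed the cultivars at 35 d, so that it measured mainly the cultivar difference at 35 d, with a smaller part of that at 15 d added, and it points to the cultivar structure of the libraries.

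Of the 25 genes that the naming rule chose, 16 were called in this test, but 4 of these were chosen by this same test, which fixes their part of the count, and the other 12 by other comparisons. Only 10 of the 16 were called with each library of 15 d and 35 d left out in turn, an alternative added after the data had been seen. The values that follow are the log2 change in HS minus that in LW. The SE beside each was derived from its size and the F statistic of the fit of all 24 libraries. Where a group had 0 counts, the size and the SE both depend on the fit and are no measured precision. MELO3C016595.2 (9.05 ± 1.9) rose in both cultivars and more in HS. MELO3C018490.2 (-8.89 ± 1.19), MELO3C029161.2 (-5.73 ± 0.59), Cucumis_melo_newGene_665 (-8.94 ± 0.91) and MELO3C011268.2 (-12.25 ± 1.23) had the higher log2 change in LW. In FPKM, Cucumis_melo_newGene_665 rose from 1.02 to 12 in HS and from 0 to 9.21 in LW. MELO3C029161.2 rose from 3.37 to 12.7 FPKM in HS and from 0.00202 to 2.05 in LW. These 2 thus gained more FPKM in HS, with LW at or near 0 at 15 d. MELO3C018490.2 and MELO3C011268.2 gained more FPKM in LW. For MELO3C018228.2 (13.27 ± 2.22) the log2 change was -11.67 in LW against 1.6 in HS, while MELO3C012873.2 (-11.25 ± 1.66) and MELO3C008342.2 (-7.28 ± 1.89) had the lower change in HS. Cucumis_melo_newGene_823 (-10.02 ± 0.44) had 0 counts in LW until 30 d and 278 counts at 35 d, while its level in HS was 35.4 FPKM at 15 d and 24.2 at 35 d. MELO3C031534.2 (-12.8 ± 3.29) was called in each case, though its libraries differed within their groups.

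The other 6 lost the call without 1 library. MELO3C010312.2 (13.07 ± 2.41) went to 5.11 (edgeR adjusted p = 1) without HS 35 d replicate 3, which held all 89 counts of that group. MELO3C034862.2 (5.12 ± 1.67) went to 1.87 and MELO3C021063.2 (15.39 ± 4.31) to 9.22, both with an edgeR adjusted p of 1, without LW 15 d replicate 2. Cucumis_melo_newGene_2767 (-3.97 ± 1.22) went to -1.79 (edgeR adjusted p = 0.29) without HS 15 d replicate 2, which held 19 of the 22 counts of its group, and to -6.7 without HS 35 d replicate 1. MELO3C013129.2 (-6.66 ± 2.44) went to -3.32 (edgeR adjusted p = 1) without HS 15 d replicate 3, and had an adjusted p of 0.053, 0.055 and 0.053 without LW 15 d replicates 1, 2 and 3. MELO3C008183.2 (11.91 ± 3.34) went to 10.3 (edgeR adjusted p = 0.14) without LW 15 d replicate 3, and to 9.94 without HS 35 d replicate 3. Among genes that were called throughout, MELO3C018490.2 moved to -7.51 without HS 15 d replicate 3, MELO3C029161.2 to -7.36 without LW 15 d replicate 1 and MELO3C008342.2 to -6.57 without LW 35 d replicate 3. MELO3C011268.2 moved to -11.48 without HS 15 d replicate 2, and MELO3C018228.2 to 11.04 without HS 35 d replicate 3 and 12.65 without LW 15 d replicate 3. MELO3C031534.2 moved to -21.52 without LW 15 d replicate 3, and lay between -13.39 and -12 with another library left out where it moved by over 1.5 times.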

How the results depend on the processing

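Library totals alone, the fit without newGene entries and every alternative for the middle days and the positions were chosen after seeing the data. All 153 totals of called genes per comparison under another scaling, filter, test, unit, block or set of fitted groups and all 108 with 1 library left out lay within 1.5 times of those reported. Of 522 counts in 1 direction, 37 moved by over 1.5 times. Library totals alone moved 10, and limma on log2(FPKM + 1), log2(FPKM + 0.1) and log2(FPKM + 1) without a filter moved 9, 8 and 10. The shares in the report show the move with library totals alone, while those of limma are not given. With at least a 2-fold change required, which by construction takes a part of the calls, the counts were 2810, 6019, 5277, 5195 and 3153 for HS minus LW at 15, 25, 30 and 35 d and over the mean, 8686, 7906, 3746 and 1571 for the 15 d to 35 d change and the steps in HS, 9533, 5220, 4803 and 3757 for those in LW, and 5158 for the difference of changes. In the counts that follow, each fit also chose its own rising and falling genes, so set and call moved together: the 4886 rising and 5175 falling genes became 2821 and 7344 with library totals alone, and 2706 and 7038, 2757 and 6969, and 2764 and 7541 in limma. Rising genes higher in HS at 25 d (2742) numbered 968 with library totals alone and 918, 965 and 880 with limma on log2(FPKM + 1), log2(FPKM + 0.1) and log2(FPKM + 1) without a filter; at 30 d (2330) they numbered 1119, 1174, 1165 and 1152. Rising genes lower in HS in the same fits numbered 730, 744, 750 and 703 at 25 d (458) and 503, 495, 489 and 465 at 30 d (679). Falling genes lower in HS at 25 d (2850) numbered 5385, 5362, 5339 and 5414. FPKM too is scaled by totals alone. On the 4886 rising genes fixed under TMM, the direction at 25 d turned in limma as it did with library totals alone. In the order of the limma fits above, 1156, 1191 and 1138 were higher in HS against 1931, 1925 and 1898 lower. At 30 d more of these genes were higher in HS than lower in each limma fit. The position difference at 25 d (0.335) was 0.233 with axis genes called in HS and 0.463 with those called in LW; at 30 d (0.299) it was 0.251 on log2(FPKM + 1) and 0.365 with axis genes called in LW; the cause was not tested. With 1 library left out these differences lay between 0.312 and 0.353 and between 0.27 and 0.323. Of 493 alternative values for genes in the comparison that named them, 491 kept their direction and call and 0 reversed. The genes were chosen for the largest changes among those called, so this outcome was largely set by the choice. MELO3C021063.2 lost its call in DESeq2 and without LW 15 d replicate 2.

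The replicate numbers did not meet the rule set for pairing, under which every same-number correlation would be over 0.1. Deviations from the group means correlated at 0.013 on average for the same number and -0.0067 for different numbers, 10 of 84 same-number pairs were over 0.1, and 13 of 24 libraries correlated best with their own number, where 8 would do so if the numbers carried no information; a weak link is not excluded. With the number as a block, 7240, 11314, 10631 and 10257 genes were called between the cultivars at 15, 25, 30 and 35 d and 8597 for the difference of changes, and no named gene changed its call. TMM-scaled FPKM, for which no gene lengths were used here, and the gene list tests with their alternatives, for which the lists had 0 members, were not run. Depth limited the folds of genes with 0 counts in a group, which are bounds from 3 counts.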

Other observations

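The tests of timing, of genes counted in 1 cultivar alone, of the left-out HS 15 d library and of other splits were read only after the results they measure had been seen; the search for entries that share the pattern of Cucumis_melo_newGene_3668 was set down before. Genes of 1 cultivar alone were few. With at least 10 counts in all 12 libraries of a cultivar and at most 3 counts in all over the other, 32 genes were found in HS and 11 in LW, of which 31 and 6 had 0 counts in the other. newGene entries were 18 of these 43 (41.9%), against 2.33% of the other genes with at least 10 counts in the 12 libraries of a cultivar (Fisher's exact test, odds ratio 30.2, 95% interval 15.4 to 58.3, p = 2.2e-18, across genes, which are not independent replicates). Among all tested genes, a difference of at least 2-fold over the mean of the days was called in 246 of 911 newGene entries (27%) and in 2907 of 18609 others (15.6%; odds ratio 2, Fisher's exact test across genes, p = 1.6e-17). With no minimum fold the order was the opposite, with 384 of 911 newGene entries (42.2%) called over the mean of the days against 11023 of 18609 others (59.2%; Fisher's exact test across genes, p = 5.2e-24), and newGene entries were called less often at each of the 4 days too, as at 15 d in 26.3% against 38.1% (p = 2.5e-13 in the same test) and at 25 d in 51.9% against 59% (p = 3e-05).

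A pair of abundant genes, chosen after their values were seen, showed the scale of the changes in the RNA pool. MELO3C024771.2 went from 14.4 ± 20 to 13500 ± 840 FPKM (SD, n = 3) between 15 d and 35 d in HS, where it took 2.7% of the counts, and from 1.71 ± 1.5 to 7170 ± 25 FPKM in LW. At 25 d it stood at 6880 ± 300 FPKM in HS and 373 ± 87 in LW. MELO3C018579.2 was at 11300 ± 1900, 6020 ± 200 and 6440 ± 3100 FPKM in LW at 15, 25 and 30 d and at 13.3 ± 7.1 at 35 d. In HS it was at 2990 ± 380 FPKM at 15 d, 655 ± 220 at 25 d and 66.1 ± 1.8 at 30 d, and at 35 d it stood at 251 ± 190, above LW (log2 difference 4.07 ± 0.58 SE, edgeR adjusted p = 8.7e-06).

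For the lead of HS at 25 d and 30 d on the axis from 15 d to 35 d, the tables argue against 1 aberrant library, since the difference at 25 d stayed at 0.312 or above with each library left out, and against single libraries of these days under the wrong cultivar, since all 12 libraries of these days expressed more of the genes found in their own cultivar alone at 15 d and 35 d. A factor common to a library moves rising and falling genes alike and cancels from the axis by construction. For the genes on this axis, a wrong factor thus does not account for the difference of 0.335 at 25 d. Which genes are on the axis rests on the factors, and no position was computed with genes chosen under library totals alone. Whether scaling acts on the lead through that choice stays open. How the lead divides between rising and falling genes also rests on the factors. At 25 d it was 0.353 and 0.322 with TMM and 0.0302 and 0.464 with library totals alone. At 30 d it was 0.251 and 0.333 against 0.142 and 0.356. A candidate explanation is that both cultivars pass a shared programme at a different pace. HS at 25 d differed from LW at 30 d in 9734 genes against 11444 from LW at 25 d, a ratio of 0.851, and from LW at 35 d in 11156. HS at 30 d differed from LW at 35 d in 9157 genes against 10701 from LW at 30 d. The HS 25 d position was already nearer that of LW 30 d than of LW 25 d. Fewer calls there were thus likely whatever the cause, and these counts cannot decide it. A different pace remains a hypothesis, and an inherited difference between the cultivars that is not one of timing stays open and untested.

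Whether the genes counted in 1 cultivar alone were not transcribed in the other or could not be counted there, for want of the sequence or through its difference from the reference, cannot be told apart here. The genes had 0 counts in the other cultivar in 37 cases, but they were chosen for at most 3 counts, which fixes the outcome.

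Cucumis_melo_newGene_3668, singled out after its values were seen, held 596531, 103255 and 8326 counts in the HS 15 d libraries, and between 5922 and 28069 in the libraries of the other groups. It was 1.9% of the first of these libraries. Only 5 entries with at least 500 counts, itself among them, shared the order and size of the difference, under the 10 set beforehand. This argues only against a source with many transcripts that are counted among these entries. Transcripts that match no entry would not be counted, so RNA of an outside source as such is not excluded. The opposite order was shared by 15 entries in HS 15 d, and the most for 1 order in another group was 38, in LW 30 d. Libraries of these groups thus differed within the group in other genes too. A source that brings a few transcripts to these entries, one whose transcripts mostly match none of them, and a difference between the fruits sampled stay open. That library did not set the number of genes called between the cultivars at 15 d, which was 6272 without it against 7334.

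For comparisons of 3 libraries with 3, 10 splits exist, too few for a share under 0.05. The real split was the only 1 of the 10 to call as many genes in each. Between the cultivars it called 7334, 11444, 10701 and 10389 genes at 15, 25, 30 and 35 d, where the highest other split called 37, 1, 0 and 2. From 15 d to 35 d it called 13895 in HS and 14468 in LW, and the highest other called 1 in each. For the steps in HS it called 13093, 8963 and 4811, with 0, 2 and 5 for the highest other, and for those in LW 10807, 10261 and 8465, with 2, 169 and 2. For the mean of the 4 days, 1 of 30 splits within days, the real one with 11407 genes, called as many, so a random grouping can be excluded at 0.05; the highest of the others called 327.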
